A study of Drosophila melanogaster with 6 samples.

How the data were processed

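Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed with an antiserum against Cmi, also called Lpt, a subunit of the Drosophila MLR complex, the fly relative of the mammalian KMT2C and KMT2D histone methyltransferase complexes. Per the labels' protocols, chromatin was fixed with formaldehyde, and immunoprecipitated and input DNA were turned into Illumina libraries. The 6 samples comprise 1 ChIP and 1 input library each from S2 cells (a Drosophila cell line of embryonic origin), from whole wandering larvae of the third instar and from whole white prepupae. A list of Cmi peaks from embryos, based on data published earlier, was analysed by the submitters in parallel and has no sample of its own in the series. Peak lists for the 3 ChIP samples and the embryo list were used. The input libraries have no values of their own here.

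The authors deposited each peak list as 3 columns, the chromosome, start and end of each peak, without any height, fold enrichment or p-value per peak. BWA, MACS2 and the genome build dm3 are named in the submitters' processing notes. Their versions, the peak threshold, the use of the input libraries in peak calling and any pooling or filtering are not given in the sources used here. The smallest gap between neighbouring peaks of a list was 50 bp in prepupae and 51 bp in the others, so no peaks of a list overlapped. Sequencing depth is unknown, because the lists hold no read counts. Without depth a difference in list length between libraries and one in binding cannot be told apart. The smallest peak was 220 bp in the prepupa list, 280 bp in the embryo list, 320 bp in the larva list and 340 bp in the S2 list, so narrow peaks entered the lists on unequal terms.

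All coordinates are on dm3 and are given counted from 1. The gene tables at hand use Release 6 of the genome, another build, so peaks were not assigned to genes, and the position of peaks relative to genes and the gene lists fixed beforehand were not analysed here. Because the lists carry no score, peak width took the place of the score wherever a ranking was needed. Width is only a stand-in for the strength of binding, since it also depends on fragment length and on how a caller joins neighbouring signals.

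A peak was counted as shared when it had at least 1 bp in common with a peak of another list. Shares are given with exact binomial (Clopper-Pearson) 95% intervals over peaks. Chance overlap was taken from 1000 random rotations, in which the other list was moved as a whole along each chromosome by a random distance, with the highest peak end found in any of the 4 lists as the chromosome's end. For classes of peak width and for the parts of the larva and prepupa lists, 100 rotations were used. All peaks that overlapped or touched were merged into regions, and each region was assigned to 1 of 15 combinations of lists. Merging can chain peaks, so the peaks of a region need not all overlap each other. Peak midpoints were counted in fixed 50 kb windows and compared with 1000 draws that placed each list's midpoints evenly along its chromosomes. Widths of shared and unshared peaks were compared with a two-sided permutation test over peaks (100000 resamples) with a bootstrap interval (1000 draws) for the ratio of medians. Shares of peaks on X against the autosomes, on 2L against 2R and on chromosome 4 against the other arms were compared between lists with two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over the 18 tests made. There is 1 library per group, so none of these tests measures the spread between animals or cultures. Every interval and p-value describes these peak lists and covers the number of peaks only, and neighbouring peaks are not independent.

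The regions named are the 10 widest peaks of each list, the 5 widest peaks of each list without an overlap in any other, the 5 densest windows of each list and the 5 regions shared by all lists with the best mean rank of width. This rule, the overlap, width and window tests, the test of X against the autosomes and the following alternatives were fixed before the data were examined: coverage of at least 50% of the shorter peak, the peak's midpoint inside the other peak, peaks wider than their list's median, the same number of widest peaks from every list, every peak set to 500 bp, the main arms alone, independent placement of peaks as chance, covered base pairs in place of peaks, and 25 kb and 100 kb windows. Chosen afterwards were the tests of 2L against 2R and of chromosome 4, the comparison of larva-only with prepupa-only peaks and its alternatives, the X share with equal list lengths, the 500 kb bins, the windows on the main arms alone and the random thinning of the embryo list to the number of S2 peaks (1000 draws). Odds ratios within width classes were pooled by the Mantel-Haenszel method.

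Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9. The scripts were tested on simulated data: in 3 simulated lists made from 6426 larva peaks the share set was recovered with a difference of 0 percentage points, an X share set to 29.6% came back as 30.1% among 5000 drawn larva peaks, and an odds ratio set to 3 within width classes came back as 3.17. The simulated lists held only copies of larval peaks with slightly moved ends and no unrelated peaks. That check therefore covers the counting alone and not overlap by chance. All 24 overlap counts checked and the 19648 merged regions were equal to those of bedtools 2.31.1.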

Results

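Binding of Cmi was mapped by ChIP-seq in S2 cells, wandering larvae of the third instar and white prepupae, with 1 ChIP library each, and set beside a list from embryos. Cmi, also known as Lpt, is a subunit of the MLR complex, a COMPASS-like assembly that contains the methyltransferase Trr and acts mainly at enhancers. The larval wandering stage and the white prepupa lie on either side of the onset of metamorphosis, which is driven by a pulse of the steroid hormone ecdysone. The embryo list held 15372 peaks, the prepupa list 9236, the larva list 6487 and the S2 list 6049. There were no replicates, and sequencing depth is unknown. Coordinates are on dm3.

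Cmi peaks were shorter in the prepupa list than in the larva and S2 lists. The median peak width was 792 bp in larvae, 711 bp in S2 cells, 537 bp in embryos and 491.5 bp in prepupae. The smallest peak had nearly the same order, with 320 bp in larvae, 340 bp in S2 cells, 280 bp in embryos and 220 bp in prepupae. Differences of library or peak calling and of binding cannot be told apart in these widths. Although the prepupa list had 2749 more peaks than the larva list, it covered less sequence, 6.86 Mb against 7.67 Mb. The S2 list covered 7.65 Mb and the embryo list 13.2 Mb. Between 95.1% of the peaks (S2 cells) and 99.1% (larvae) lay on the main arms 2L, 2R, 3L, 3R, 4 and X.

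The first comparison asked how far Cmi binding was retained between the larva and the prepupa. Of the 6487 larval peaks, 4423 (68.2%, 95% interval 67.0 to 69.3) overlapped a prepupal peak, 5.87 times the 11.6% found on average over 1000 rotations. In the other direction, 5681 of the 9236 prepupal peaks (61.5%, 60.5 to 62.5) overlapped a larval peak, 6.41 times the chance level of 9.59%. Retention rose with peak width. Of the widest of 4 equal width classes of larval peaks (1464 bp or more), 97.3% (96.4 to 98.1) were present in prepupae, against 40.8% (38.4 to 43.3) of the narrowest class. The chance levels for these classes were 17.2% and 8.10%. One broad larval peak often corresponded to several prepupal peaks: 1191 of the 4423 retained larval peaks (26.9%) overlapped 2 or more. The difference in list length of 2749 peaks divided into 1258 among overlapping peaks (5681 prepupal against 4423 larval) and 1491 among peaks without a counterpart (3555 against 2064).

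Peaks found at only one of these consecutive stages differed in their relation to the embryo. Of the 2064 larval peaks without a prepupal counterpart, 61.6% (59.5 to 63.7) overlapped an embryonic peak, against 16.7% by chance. Of the 3555 prepupal peaks without a larval counterpart, 33.4% (31.8 to 34.9) did so, against 15.3% by chance. The odds ratio was 3.21 (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 3.47e-94 over 2 tests). The same direction held for S2 peaks, which overlapped 31.5% (29.5 to 33.5) of the larva-only and 15.7% (14.5 to 16.9) of the prepupa-only peaks (odds ratio 2.47, Fisher's exact test, adjusted p = 1.57e-42). Peaks present at both stages overlapped the embryo list in 69.5% (larval peaks) and 66.9% (prepupal peaks) of cases and the S2 list in 50.7% and 51.6%. Peaks found at one stage were narrower, with medians of 498 bp in larvae and 356 bp in prepupae against 1095 bp and 658 bp for the shared ones. The p-values compare these lists and not replicate animals.

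The next comparisons placed the embryo and the S2 cell line against the later stages. Embryonic peaks accounted for 67.0% (65.9 to 68.2) of larval, 54.0% (53.0 to 55.0) of prepupal and 55.9% (54.7 to 57.2) of S2 peaks, where chance gave 20.5%, 17.6% and 20.6%. Of the embryonic peaks, 56.0% (55.2 to 56.8) overlapped none of the other lists, 30.4% (29.7 to 31.2) overlapped a larval, 28.0% (27.3 to 28.7) a prepupal and 24.6% (24.0 to 25.3) an S2 peak. S2 peaks overlapped larval peaks in 47.4% (46.2 to 48.7) and prepupal peaks in 41.1% (39.9 to 42.3) of cases, with chance levels of 11.2% and 11.5%. Conversely, 44.6% (43.4 to 45.8) of larval and 37.8% (36.8 to 38.8) of prepupal peaks overlapped an S2 peak. All 12 directed overlaps lay above the highest of their 1000 rotations, by 2.63 to 6.41 times the mean. Relative to chance, the embryo list was the lowest match of each other list, at 3.27 times for larval, 3.07 for prepupal and 2.71 for S2 peaks. S2 peaks stood at 4.24 times chance in the larva list and 3.59 times in the prepupa list. A higher chance level leaves less room for such a ratio. Which list held the largest share changed under some alternatives. With the same number of widest peaks from each list, S2 peaks overlapped larval peaks more often than embryonic ones (46.4% against 42.5%), and with the midpoint rule larval peaks overlapped the embryo list (56.7%) more often than the prepupa list (55.0%). With every peak set to 500 bp, embryonic peaks overlapped prepupal peaks (22.3%) more often than larval ones (21.9%).

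**Figure D1:**
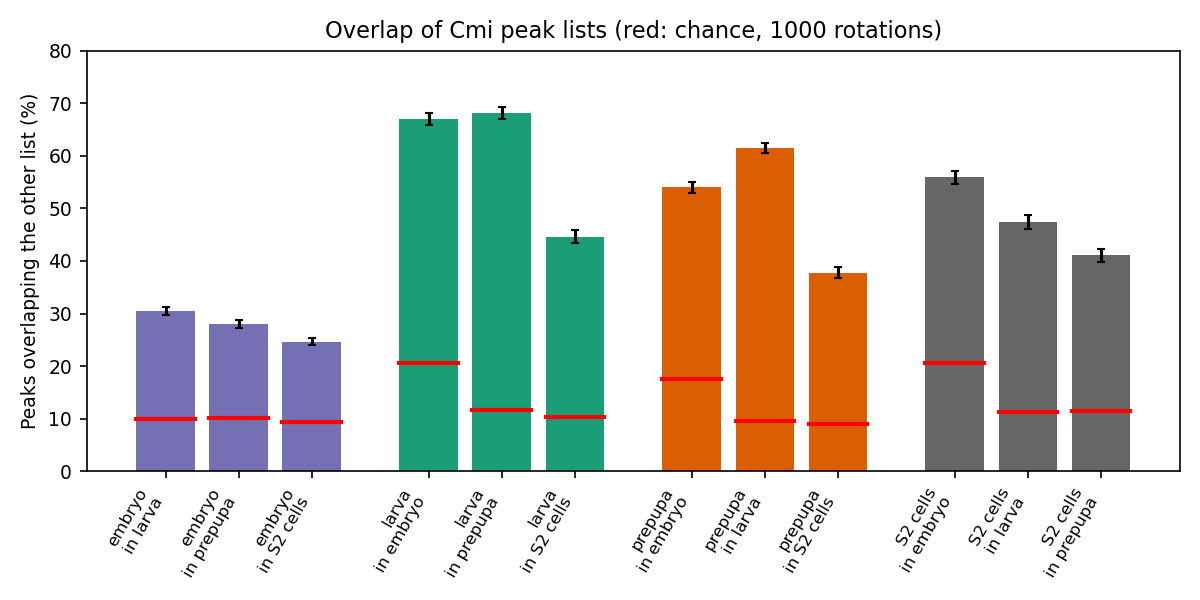
Percentage of the peaks of each list (bars, by colour) that overlap a peak of another list by at least 1 bp, with exact 95% binomial intervals over peaks (black) and the mean of 1000 rotations (red lines). Every bar stands above its chance level, and the highest are larval peaks in the prepupa list (68.2%) and in the embryo list (67.0%).

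Merging the 4 lists gave 19648 regions with a Cmi peak in at least 1 of them. A core of 1539 regions (7.83%) had a peak in all 4, where independent rotation gave 51.5 on average and at most 77. A further 1096 regions had a peak in embryo, larva and prepupa but none called in S2 cells (173 by chance). Peaks in larva and prepupa alone were found in 749 regions (433 by chance, within the range of 365 to 815 over rotations). A peak that was not called does not show that Cmi was not bound. Below the lowest rotation lay embryo with larva (659 against 753) and embryo with prepupa (671 against 822). So did larva with S2 (89 against 227), prepupa with S2 (108 against 288) and embryo with prepupa and S2 (101 against 107). Regions of a single list numbered 8603 in embryos, 2056 in prepupae, 1949 in S2 cells and 618 in larvae, each below the lowest of the rotations. This order changed with list length: with the same number of widest peaks from every list they numbered 2189, 1186, 2455 and 933. Larval peaks were the most often shared: 9.53% (8.82 to 10.3) of larval peaks overlapped no other list, against 22.3% (21.5 to 23.2) in prepupae, 32.3% (31.1 to 33.4) in S2 cells and 56.0% (55.2 to 56.8) in embryos.

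**Figure D2:**
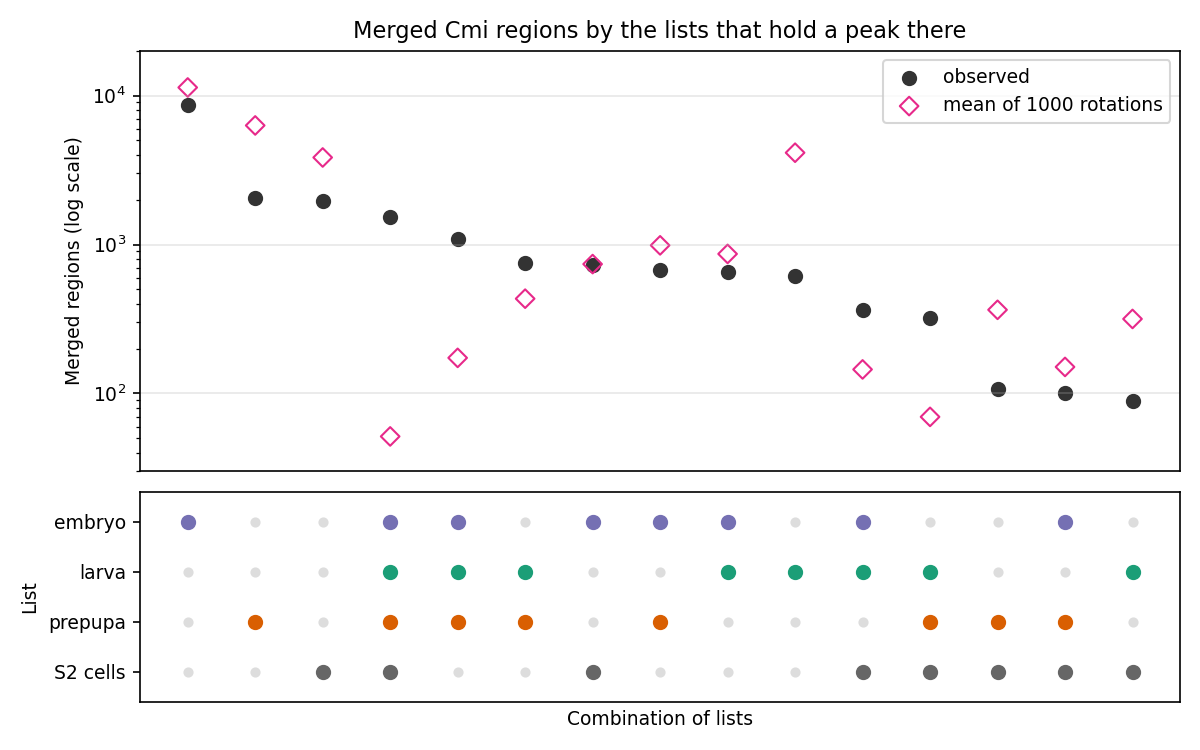
Number of merged Cmi regions (log axis, upper panel) for each of the 15 combinations of lists marked by coloured dots in the lower panel, with the mean of 1000 rotations as open diamonds. The 1539 regions with a peak in all 4 lists have the highest ratio of observed to chance number, which was 51.5 regions. Single-list regions lie below chance, as do some combinations of 2 or 3 lists. The combinations exclude each other, so more sharing among all lists lowers these counts.

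Shared peaks were broader than unshared ones in every list. The median width of peaks that overlapped any other list was 849 bp against 434 bp in embryos, 866 bp against 442 bp in larvae, 565 bp against 348 bp in prepupae and 886.5 bp against 553 bp in S2 cells. The ratios were 1.96 (95% bootstrap interval 1.90 to 2.03), 1.96 (1.85 to 2.06), 1.62 (1.56 to 1.69) and 1.60 (1.53 to 1.69). Each had p = 1e-05 in the permutation test over peaks, the smallest that 100000 resamples can give. A broad peak also meets another list more often by chance, as the class values above show.

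Nearly all of the broadest peaks had a counterpart in every other list, but how far their width alone gives this was not tested. Of the 40 peaks that are the 10 widest of their list, 38 overlapped all 3 other lists and 2 overlapped 2 others. Chance overlap was not computed for peaks this wide. In the embryo list it was already 29.0% for the widest class of larval peaks and 31.0% for that of S2 peaks. These 40 peaks lay in 34 distinct places, 5 of which held more than 1 of them, and 2 of the prepupal peaks were outside the main arms, on the mitochondrial genome (1 to 9337) and on the unplaced sequence U (5288399 to 5297880). Of the 38 peaks on the main arms, 36 overlapped all 3 other lists. The region with the best mean width rank among those shared by all lists was on X from 2186055 to 2203726, where the widest peak spanned 11339 bp in embryos, 14933 bp in larvae, 5026 bp in prepupae and 17672 bp in S2 cells. The next was on 3R from 12053712 to 12082494, with widest peaks of 15263, 9614, 4974 and 17793 bp in the same order. The other 3 were on 2R from 7067781 to 7095584, on 2L from 2749090 to 2758313 and on 2R from 5324847 to 5334607. In the first of these, the widest peaks were 6867 bp in embryos, 7079 bp in larvae, 6325 bp in prepupae and 12897 bp in S2 cells. That merged region is thus a chain of overlapping peaks, longer than any single one. The widest peak of the prepupa list was on 2L from 5289794 to 5300759 (10966 bp), followed by 3L from 17961350 to 17972129 (10780 bp). Of the 10 widest larval peaks, 6 were on X, against 2 in each of the other lists. The widest S2 peak, on 3L from 621546 to 642877, reached 21332 bp. Peaks without any counterpart were smaller. The widest such peak measured 7835 bp in S2 cells (X from 21594860 to 21602694), 5026 bp in embryos (2L from 4349293 to 4354318), 2092 bp in larvae (3L from 3928611 to 3930702) and 1927 bp in prepupae (3L from 1456779 to 1458705).

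The X chromosome held a larger part of Cmi peaks in larvae and prepupae than in embryos and S2 cells. Its share was 17.4% (16.4 to 18.3) in larvae and 16.2% (15.5 to 17.0) in prepupae, against 11.1% (10.6 to 11.6) in embryos and 11.3% (10.5 to 12.1) in S2 cells. X makes up 18.6% of the span of the main arms. The odds of an arm peak lying on X rather than on an autosome were 1.66 times higher in larvae than in embryos (Fisher's exact test, adjusted p = 5.74e-32) and 1.54 times higher in prepupae than in embryos (exact adjusted p = 1.40e-28). Against S2 cells they were 1.57 times higher in larvae (exact adjusted p = 1.26e-17) and 1.46 times higher in prepupae (exact adjusted p = 3.57e-14). Larvae and prepupae did not pass the test against each other (odds ratio 1.08, exact adjusted p = 0.111), and neither did embryos and S2 cells (odds ratio 0.94, exact adjusted p = 0.274). The embryo data come from an earlier publication and the S2 cells are a single line, so stage, source and library cannot be separated in these contrasts.

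S2 cells stood apart in the division of peaks among the autosomes. They had 0.57 peaks on 2L for each peak on 2R, where embryos had 0.93, prepupae 0.88 and larvae 0.86. The odds of 2L against 2R were 1.65 times higher in embryos than in S2 cells (exact adjusted p = 5.61e-23), 1.55 times higher in prepupae (exact adjusted p = 4.52e-15) and 1.51 times higher in larvae (exact adjusted p = 1.38e-11). The small chromosome 4, which is rich in heterochromatin, carried 156 peaks in embryos, 72 in larvae, 52 in prepupae and 14 in S2 cells, or 1.01% (0.86 to 1.19), 1.11% (0.87 to 1.40), 0.56% (0.42 to 0.74) and 0.23% (0.13 to 0.39) of each list. The odds of a peak lying on chromosome 4 were 1.97 times higher in larvae than in prepupae (exact adjusted p = 0.000362) and 4.64 times higher in larvae than in S2 cells (exact adjusted p = 5.36e-09).

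**Figure D3:**
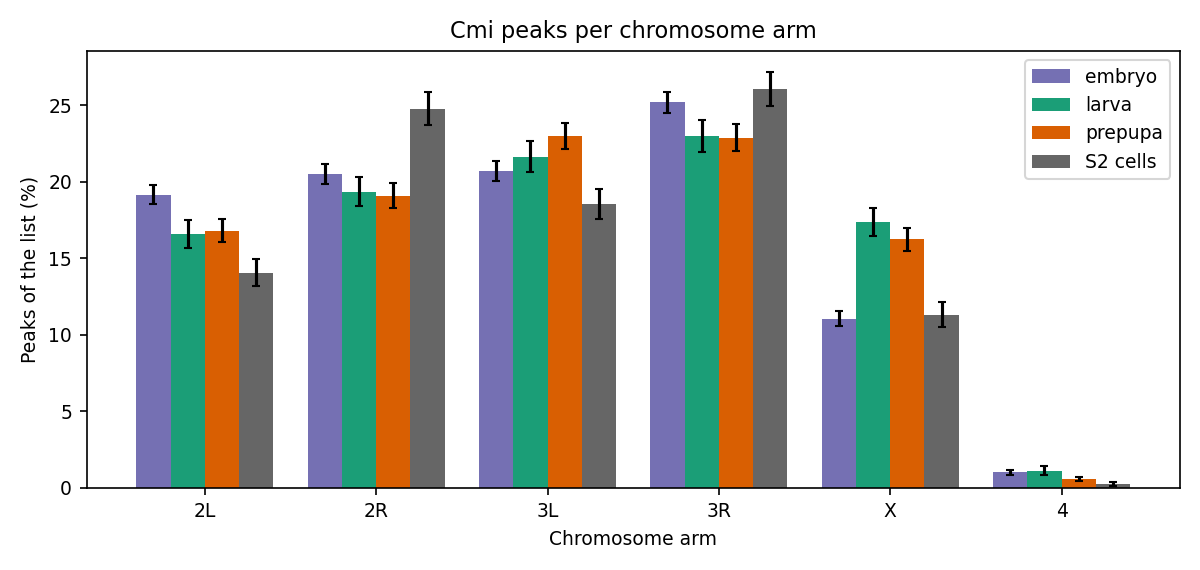
Percentage of the peaks of each list on each chromosome arm, with exact 95% binomial intervals over peaks. On X, larvae (17.4%) and prepupae (16.2%) stand above embryos (11.1%) and S2 cells (11.3%), and S2 cells are highest on 2R (24.8%) and lowest on 2L (14.1%).

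Some dense clusters of Cmi peaks stood out in a single list and others in several. These are counts of peaks, which also depend on list length and on how bound sequence is divided into peaks. Of the retained larval peaks, 26.9% overlapped 2 or more prepupal peaks, and covered sequence per window was not compared. The most crowded 50 kb window of the prepupa list, on 3L from 16150001 to 16200000, held 34 peaks, against 13 in larvae, 7 in embryos and 4 in S2 cells. In 1000 random placements the highest count of any prepupal window was 18. Neighbouring windows on 3R from 17400001 to 17500000 held 26 and 25 prepupal, 19 and 23 embryonic, 10 and 12 larval and 7 and 6 S2 peaks. The larval maximum of 20 peaks, on 3L from 8650001 to 8700000, lay in a window with 18 in prepupae, 13 in S2 cells and 11 in embryos. The window on 3L from 17950001 to 18000000 held 21 peaks in prepupae and 16 in S2 cells, above the highest random counts of 18 and 15. Larvae had 15 peaks there, above their highest random count of 14 but not above that of 15 with the main arms alone, and embryos had 15, below theirs of 24. The embryonic maximum of 31 peaks was on 2R from 19750001 to 19800000, where larvae had 6, S2 cells 4 and prepupae 3. A window on 3L from 15300001 to 15350000 held 25 embryonic peaks and 0 in each other list. The S2 maximum of 23 peaks was on 2R from 1600001 to 1650000, where embryos had 17, prepupae 3 and larvae 1. Windows above the highest random count numbered 23 in prepupae, 19 in S2 cells, 5 in embryos and 4 in larvae, but numbers and order were not stable. They were 6, 7, 5 and 2 at 25 kb, where all 10 larval mitochondrial peaks fell into 1 window in every draw, which kept the larval random maximum from falling below 10, and 31, 15, 23 and 7 at 100 kb. On the main arms alone, with new draws, they were 28, 19, 8 and 3 at 50 kb, 14, 5, 1 and 2 at 25 kb and 31, 25, 10 and 6 at 100 kb. Among peaks wider than their list's median, against random placements of those peaks, they were 5, 2, 1 and 0.

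**Figure D4:**
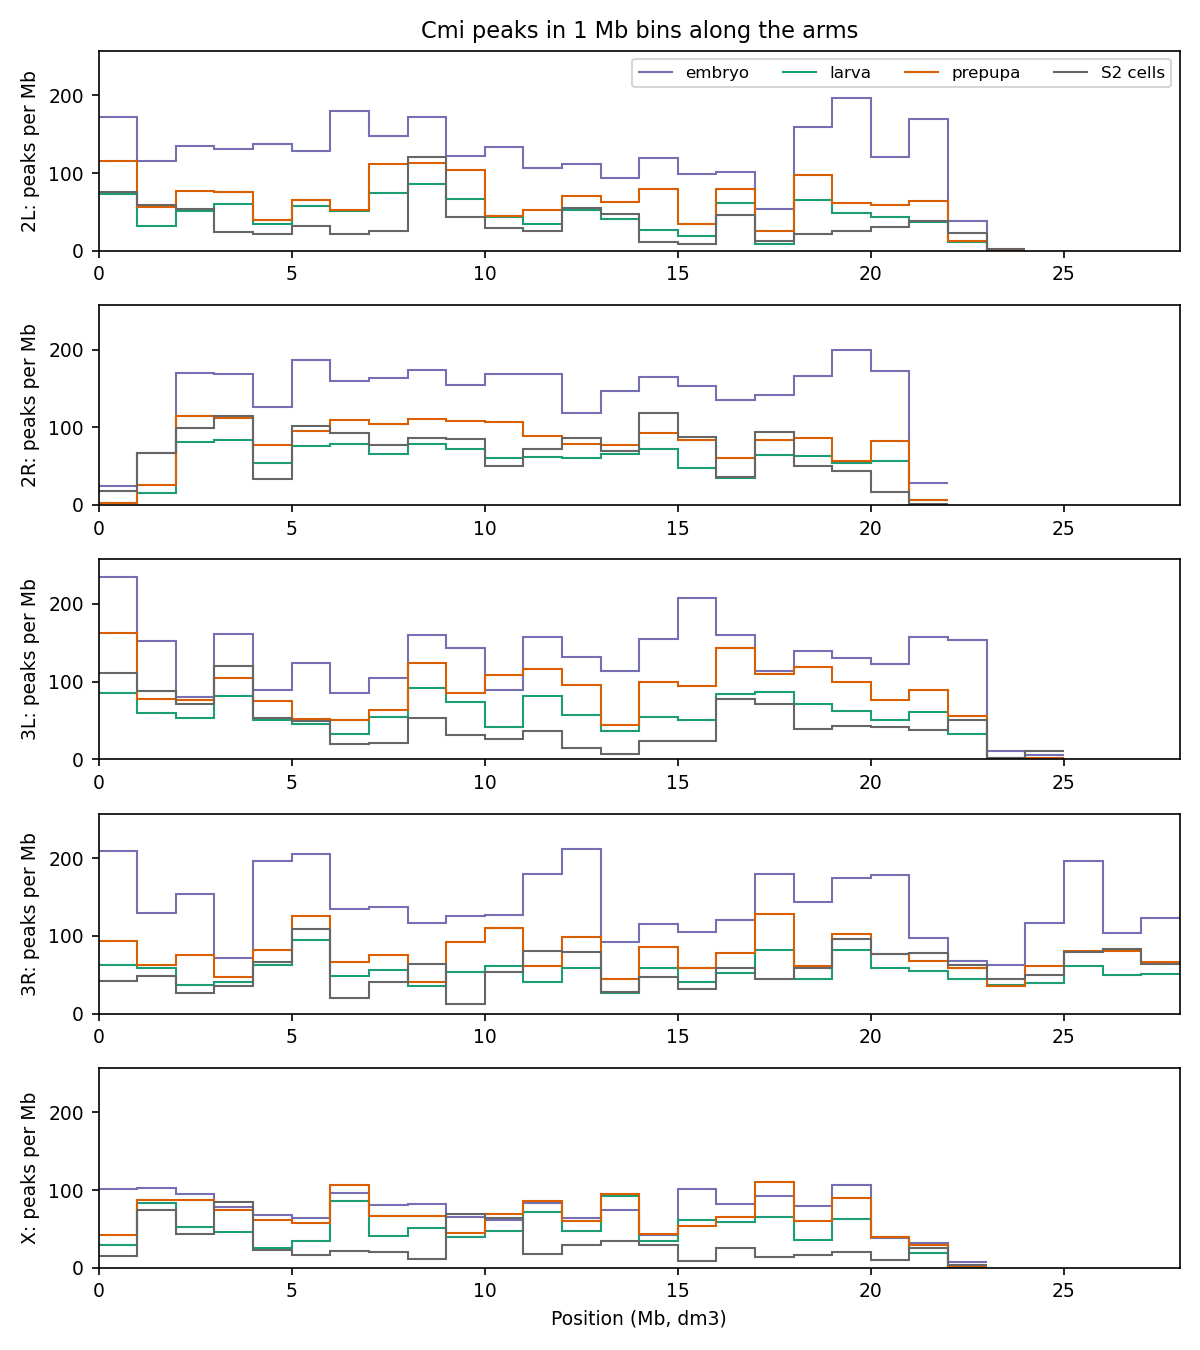
Number of Cmi peaks whose midpoint lies in each 1 Mb bin along the arms 2L, 2R, 3L, 3R and X (position in Mb on dm3), one line per list. The S2 line rises above both larva and prepupa lines in places such as 2R from 1 to 2 Mb (67 peaks, as in embryos, against 16 and 26) and lies far below them in others such as 3R from 9 to 10 Mb (12 against 53 and 92).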

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

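The comparison of larva-only and prepupa-only peaks and its alternatives, the X share with equal list lengths and the windows on the main arms alone were chosen after the peak lists had been seen. Of the overlap shares (larva in prepupa, prepupa in larva, larva in embryo, prepupa in embryo, then S2 in embryo, larva and prepupa), most left their binomial intervals. In that order they were 64.6, 57.1, 62.8, 49.7, 51.1, 43.4 and 38.5% with at least 50% of the shorter peak covered, and 55.0, 55.4, 56.7, 46.2, 43.7, 38.4 and 30.2% with the midpoint rule. With every peak set to 500 bp they were 60.5, 45.1, 51.0, 38.4, 38.8, 31.3 and 31.7%. With peaks wider than their list's median they were 74.7, 63.5, 68.4, 55.5, 56.2, 51.0 and 47.9%, and with equal numbers of widest peaks 60.3, 70.9, 54.4, 46.8, 42.5, 46.4 and 35.7%. On the main arms the S2 shares were 58.3, 49.7 and 42.9%. Independent placement of peaks kept the chance levels within the range of the rotations for each of these 7. Regions in all 4 lists fell to 918 with peaks wider than the median, which leaves fewer peaks by construction. They fell to 1059 with every peak set to 500 bp, which drops no peak, and to 1201 with equal numbers of widest peaks. With peaks wider than the median, single-list regions were 4247 (embryo), 245 (larva), 975 (prepupa) and 886 (S2). With equal numbers of widest peaks they were 2189 in embryos, 933 in larvae, 1186 in prepupae and 2455 in S2 cells, so that the embryo list no longer had the most, and with 500 bp peaks 1030 were in larvae alone. The X share moved to 12.2% (embryo) and 18.9% (larva) with wide peaks, to 12.4% (embryo), 19.3% (larva) and 12.4% (S2) of covered base pairs, and to 12.8% (embryo) with equal list lengths, and larvae and prepupae stayed above embryos and S2 cells in each. Windows above chance numbered 2 (larva), 6 (prepupa) and 7 (S2) at 25 kb, 23 (embryo) and 7 (larva) at 100 kb, and 1 (embryo), 0 (larva), 5 (prepupa) and 2 (S2) with wide peaks. On the main arms alone they were 8 (embryo) at 50 kb, 1 (embryo), 2 (larva), 14 (prepupa) and 5 (S2) at 25 kb, and 10 (embryo) at 100 kb. These counts are read against the single highest of 1000 draws, so they move with the draws too. The width ratio of shared to unshared peaks was 1.85 in embryos and 1.72 in larvae with the midpoint rule. The embryo overlap of larva-only peaks was 54.5% with 50% coverage, 52.3% with midpoints, 58.7% with wide peaks, 46.7% with equal numbers and 50.9% with 500 bp peaks, and that of prepupa-only peaks was 30.2, 28.7, 32.0, 19.7 and 29.1%, lower each time. Except where fewer peaks or a stricter rule account for a move by construction, the cause was not tested. The best match by share changed for larval peaks with midpoints (embryo above prepupa) and for S2 peaks with equal numbers (larva above embryo). It also changed for embryonic peaks at 500 bp (prepupa above larva). A comparison of scores within width classes, the promoter definitions and the settings for gene lists were not run, because the lists carry no scores and peaks were not assigned to genes. Depth limits everything said of absent peaks: without read counts or peak heights, a peak missing from a list was not called there, which does not show that Cmi was not bound.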

Other observations

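The tests of the uneven S2 list, with both bin sizes and with the thinned embryo list, were chosen only after that pattern had been seen, and every pattern was noticed in the lists on which it was tested. Very broad Cmi peaks were most frequent in the S2 list. That list also had the largest minimum width, so peak calling and binding cannot be told apart here. Peaks of 5 kb or more made up 3.04% (2.62 to 3.51) of the S2 list (184 peaks), 1.51% (1.23 to 1.84) of the larva list (98), 0.65% (0.53 to 0.79) of the embryo list (100) and 0.34% (0.23 to 0.48) of the prepupa list (31). Peaks of 10 kb or more numbered 31 in S2 cells, 9 in larvae, 8 in embryos and 2 in prepupae. Sequences annotated as heterochromatic or left unplaced in the assembly held 4.86% (4.33 to 5.43) of S2 peaks, 2.30% (2.07 to 2.55) of embryonic, 1.36% (1.14 to 1.62) of prepupal and 0.79% (0.59 to 1.03) of larval peaks. The mitochondrial genome carried 10 larval, 6 embryonic, 5 S2 and 3 prepupal peaks, which covered 10824, 5514, 13459 and 14314 bp of it. Whether Cmi was bound there was not tested, and these peaks are counted among the peaks of each list.

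Larval peaks without a prepupal counterpart overlapped the embryo list far more often than prepupal peaks without a larval one, with an odds ratio of 3.21 (95% interval 2.87 to 3.59). The values argue against a difference in peak width in bp between the lists as the whole cause. The Mantel-Haenszel odds ratio over width classes was 2.99 (2.64 to 3.39), and the larval share was higher in each of the 8 classes with peaks of both lists. Classes without peaks of both, among the 10 set, were left out. Because the smallest peaks of the lists differed, an equal width need not mean an equal rank within a list. A longer prepupa list that reaches weaker sites is argued against as far as width reflects strength: with only as many of the widest prepupal peaks as there are larval peaks, the odds ratio was 3.01 (2.66 to 3.40). What stays open is whether the larva-only sites are weakly bound in prepupae and fell short of the threshold, and whether the prepupa list holds more false calls, because neither heights nor replicates can be used. A loss of embryonic sites together with a gain of sites specific to the prepupa is a biological hypothesis that these lists may serve to rank for a replicated test.

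The share of peaks on X was at least 4.92 percentage points higher in larvae and prepupae than in embryos and S2 cells. It was not a matter of list length alone, because with the same number of widest peaks per list the gap was 3.67 points (16.4% in prepupae against 12.8% in embryos). It was not carried by a few dense stretches alone either, because without the 44 X windows densest in larvae and prepupae the gap was 2.29 points (11.3% in prepupae against 9.04% in embryos). A difference of stage and tissue, and a difference of study or library between the embryo list and the others, remain open and were not tested. How input DNA entered the peak calls, which could set the level on X in material with differing copies of X, is not given in the sources used here.

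The S2 list was uneven along the arms: the log2 ratio of S2 peaks to larval and prepupal peaks over 115 bins of 1 Mb had an SD of 0.77, against 0.38 for the same ratio of embryonic peaks, a ratio of SDs of 2.05 (95% bootstrap interval 1.72 to 2.44). A shorter list varies more by counting alone, but with the embryo list thinned to the number of S2 peaks the ratio was 1.88 (1.56 to 2.28), which argues against an unevenness common to all lists. Neighbouring bins were correlated for S2 cells (r = 0.18 over 110 neighbouring pairs within arms, one-sided permutation p = 0.007 over 10000 shuffles of the bins) and not detectably for embryos (r = -0.06, permutation p = 0.55), while at 500 kb both were correlated, with r = 0.32 for S2 cells (p = 0.0001, the smallest that the shuffles can give) and 0.13 for embryos (p = 0.013). The correlations were weak and covered directly neighbouring bins only, so they do not show how long any blocks are. Segments of differing copy number, which are common in cell lines, would make neighbouring bins alike. Each arm was centred on its own mean, so the 2L and 2R difference was not part of this test. Domains of activity specific to the cell type would make neighbouring bins alike too. The read depth of the S2 input library along the arms would be the test between copy number and such domains, and it was not analysed here.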
